A study of Rattus norvegicus with 22 samples.

How the data were processed

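The series holds small RNA libraries from the hippocampus of male Long Evans rats, 11 from rats given CPF and 11 from rats given vehicle. RNA came from the CA1 region and libraries were made with a TruSeq small RNA kit and sequenced on a HiScanSQ, per the labels' protocols. The labels number the study days of the same 21 doses in different ways, and describe a cohort with fear conditioning and a cohort without it, but do not say which library belongs to which cohort.

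The deposited files give a value per miRNA name in reads per 1000000 (RPM), per the file headers, computed by the authors relative to the reads assigned to miRNAs. The submitters' processing notes name CASAVA 1.8.2, cutadapt 1.2, Bowtie, Partek 6.6 and the rat build rn4, without their roles. The miRNA annotation, the treatment of reads that match several loci and the use of strand are not given in the sources used here. Reads from near-identical copies, such as miR-181a and miR-181a-5p or miR-128 and miR-128-3p, which stand under separate names, and from miRNA genes that overlap another (among those named here miR-338, miR-29a, miR-29c, miR-125b, miR-181a-1, miR-24-1, miR-133a, miR-434, miR-31, miR-369, miR-126a and let-7f), are therefore uncertain in their split. The strands of the overlapping genes were not compared here. No genome coordinates are printed, since the gene table at hand is of another build (GRCr8). It was used only for which miRNA genes neighbour or overlap each other. Some overlapping genes had equal group means and SDs under both names. Examples are miR-210-3p and miR-3574, miR-369-5p and miR-3578, and let-7a and miR-3596a (pairs named after their values were seen). The tested miRNAs thus include names that are not separate measurements.

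A full file has 484 rows with 468 distinct names. 13 names stand on 29 rows, and their RPM were summed. The file of control replicate 2 ends after 448 rows, so its other 36 rows, which hold 967 RPM, were treated as missing and not as 0. Low values are multiples of a step in each library. Since 1193 values are 2 steps and only 54 are a single step, a read was taken as 2 steps, which gives 47844 to 94980 reads per library. Within 0.02 RPM, 96.3 to 98.7% of the values of a library are whole steps and 92.8 to 97.4% whole reads. For count tests the recovered reads were rounded to whole numbers, over 432 names held by all libraries. No 2 libraries agreed within sampling noise (lowest chi-square per degree of freedom 2.42).

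The design fixed beforehand provided a count test if the files held counts and a test on a log scale if they held a normalized unit. As they hold RPM, limma 3.58.1 with a trend, in R 4.3.3, was fitted to log2(RPM + 1) for 273 miRNAs with at least 10 RPM in at least 11 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05, two-sided. Fold changes are on this scale, where those of low miRNAs can be larger or smaller than the ratio of mean RPM, and none is given where both groups average under 3 reads. The contrasts between the first digits of the library codes used the same values in a model with all 4 digits. 16 lists of miRNAs were tested as sets with camera (preset correlation 0.01, at least 3 members, members held by all libraries), with an estimated correlation and with fry as alternatives. fry asks whether the members of a list move, on balance, in a single direction. The rule for matching names left miR-9a and miR-218a out of the neuron-enriched list. Shares of RPM and names detected (20 measures) were compared by a two-sided permutation test of the mean difference with 100000 resamples in scipy 1.17.1.

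The miRNAs named in the text follow a rule fixed in advance. It takes up to 10 that rose and 10 that fell past the threshold with the smallest p, those with the smallest unadjusted p until 5 of a direction are named, the 5 of highest mean over all libraries, the 2 members of each list with the highest such mean and any that passed, and the 3 of smallest p in each digit contrast.

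The tests were tried on simulated tables of 418 miRNAs with 11 libraries against 11 at the real depths, changed ones at a mean of at least 5 reads. For CPF against control limma found 66.5% of 1.5-fold, 90% of 2-fold and 100% of 4-fold changes, with 3.39% false among its calls, and edgeR 70%, 79% and 80.5%, with 2.96% false. 0 of 10 tables without changes gave a call. The simulated spread followed the trend over abundance, with no spread particular to a miRNA and no shift shared by the miRNAs of a library. The shares found may therefore be higher, and the false share lower, than in the real data. A changed miRNA that a filter removed counted as not found.

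Alternatives were other pseudocounts and filters, median-ratio scaling, unsummed rows, edgeR 4.0.16 (TMM, RLE, upper quartile, totals only, other filters, robust), DESeq2 1.42.0 and limma-voom on the recovered reads, the replicate number as a block, the code digits, and leaving out libraries. Settings and rules listed as planned were fixed before the data were examined.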

Results

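Small RNA was sequenced from the hippocampus of 14-week-old male Long Evans rats, a pigmented outbred laboratory strain. The treated rats had received chlorpyrifos (CPF), an organophosphate insecticide that blocks the acetylcholine-degrading enzyme acetylcholinesterase, at 10 mg/kg under the skin each day for 21 days. The controls had received the peanut oil vehicle for the same 21 days. There were 11 libraries per group. The labels give no animal identifiers, so the p-values measure the spread between these libraries. Each library was reported as reads per 1000000 (RPM) for up to 468 distinct microRNA (miRNA) names. The depth recovered from the steps between low values was small, 47844 to 94980 miRNA reads per library (control 70880 ± 6709, SD, n = 11, CPF 74134 ± 12857, SD, n = 11). A single read was therefore worth 10.5 to 20.9 RPM, and 3 reads, taken as the floor, 31.6 to 62.7 RPM. Reads made without molecular identifiers are not independent molecules, so this floor covers counting error only.

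In both groups a few miRNAs filled most of each library. The vessel- and muscle-rich miR-143-3p alone took 26.0 ± 1.75% of RPM in control and 26.8 ± 2.62% in CPF libraries (SD, n = 11 each), and the 10 most abundant names of each library took 77.3 ± 0.515% and 76.6 ± 1.31%. By the mean over all 22 libraries the next most abundant were miR-27b-3p (153663 ± 11013 RPM in control, 156103 ± 13819 in CPF), miR-30d-5p (73180 ± 3222 and 69898 ± 5541), miR-29a-3p (54741 ± 8529 and 53264 ± 7953) and the oligodendrocyte-rich miR-338-3p (55889 ± 11908 and 50330 ± 13800). None of these 5 passed the test between groups, with log2 fold changes of -0.17 to 0.04. The counting is not stated to use strand, and miR-338 and miR-29a come from genes that overlap another miRNA gene, so the split of reads with that partner is uncertain.

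The central comparison asked which hippocampal miRNAs differed after 21 days of CPF. 2 miRNAs, miR-132-3p and miR-212-5p, were higher in CPF libraries, and none passed the threshold in the other direction. miR-132-3p, an activity-induced neuronal miRNA known to target the acetylcholinesterase transcript, rose from 698 ± 159 to 1292 ± 362 RPM (SD, n = 11 each), or 1.83-fold (95% CI 1.47 to 2.28). It lay above the control median in 10 of 11 CPF libraries and above the highest control in 9. miR-212-5p, made from the gene next to miR-132 on the chromosome, rose from 820 ± 106.3 to 1101 ± 129 RPM, or 1.34-fold (95% CI 1.19 to 1.52). It lay above the control median in 11 of 11 CPF libraries and above the highest control in 8. In recovered reads these levels were 49 and 95 reads per library for miR-132-3p and 58.3 and 81.2 for miR-212-5p. With limma on log2(RPM + 1), the log2 fold changes were 0.87 (SE 0.154, adjusted p = 0.00131) and 0.43 (SE 0.0864, adjusted p = 0.00456). These were 2 of 273 miRNAs tested, with 18 at an unadjusted p under 0.05. edgeR on recovered reads called 4 of 140, adding miR-409b and miR-1298, and DESeq2 called 5 of 418, adding also miR-448-3p (named after its values were seen).

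**Figure D1:**
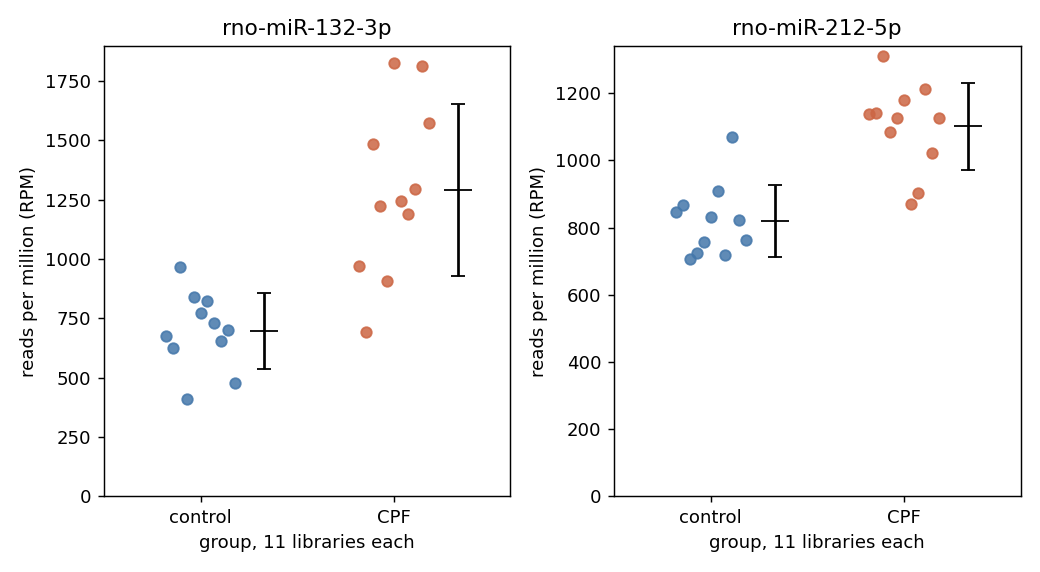
Level of miR-132-3p and miR-212-5p in RPM, each point a library, with the mean and SD of the 11 libraries of a group as a black bar. miR-132-3p spans 408.6 to 967 RPM in control and 691 to 1827 RPM in CPF, and miR-212-5p 707 to 1070 RPM and 869 to 1310 RPM.

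The libraries of each group carry code numbers whose first digit splits them, into digits 1 (n = 5) and 4 (n = 6) in control and digits 3 (n = 6) and 6 (n = 5) in CPF. The labels do not say what the digit stands for, and do not match digits across groups. Setting 3 against 1 and 6 against 4, by the order of the digits, was a choice made here. The other matching, 3 against 4 and 6 against 1, was not run. Between digits 3 and 1, miR-212-5p was higher by 0.58 on the log2 scale (limma adjusted p = 0.0235) and miR-132-3p by 0.73 without passing (adjusted p = 0.484). Between digits 6 and 4, miR-132-3p was higher by 1.04 (limma adjusted p = 0.00121) and miR-212-5p by 0.27 without passing (adjusted p = 0.745). The CPF effect itself was not shown to differ between these pairings. The difference was -0.30 for miR-132-3p (95% CI -0.94 to 0.33, limma adjusted p = 0.865) and 0.31 for miR-212-5p (95% CI -0.04 to 0.66, adjusted p = 0.865).

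Among miRNAs that did not pass, the smallest p-values with higher values in CPF belonged to miR-409b, miR-34b-3p and miR-1298. miR-409b was at 8188 ± 763 RPM in control and 9581 ± 958 in CPF (log2 fold change 0.23, limma adjusted p = 0.127), and it passed without control replicate 6 (adjusted p = 0.0417) or without CPF replicate 1 (adjusted p = 0.0213). miR-1298 was at 133 ± 77.6 and 795 ± 1243 RPM (log2 fold change 1.61, adjusted p = 0.266). Without CPF replicates 7, 8 and 9, which hold its highest values, its log2 fold change was 0.65 (95% CI -0.06 to 1.36). miR-34b-3p was under the floor in both groups, at 3.18 ± 6.82 RPM in control (n = 10) and 18.8 ± 12.1 in CPF (adjusted p = 0.188). The smallest p-values with lower values in CPF were those of miR-133a-3p, miR-1249, miR-128-3p, miR-24-1-5p and miR-345-3p. Of these, miR-1249 was at 1200 ± 231 RPM in control and 1006 ± 115 in CPF (log2 fold change -0.24, adjusted p = 0.533), miR-128-3p at 693 ± 74.8 and 572 ± 171 (-0.33, adjusted p = 0.533) and miR-345-3p at 172 ± 37.4 and 132 ± 56.7 (-0.45, adjusted p = 0.677). The near-identical and more abundant miR-128 was at 7674 ± 1352 and 7558 ± 1626 RPM (log2 fold change -0.03, limma adjusted p = 0.972). The split of reads between miR-128 and miR-128-3p is uncertain. The muscle miRNA miR-133a-3p (17.5 ± 13.4 and 4.91 ± 6.84 RPM, adjusted p = 0.377) and miR-24-1-5p (39.6 ± 18 and 19.5 ± 10.1 RPM, adjusted p = 0.533) averaged under 3 reads in each group.

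**Figure D2:**
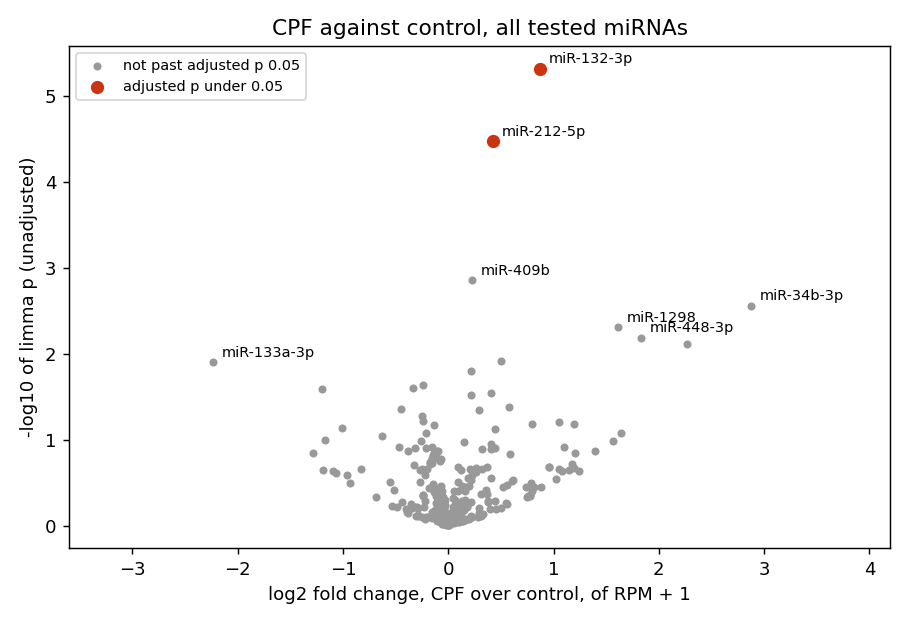
Fold change against p-value for the 273 tested miRNAs, each point a miRNA, with the log2 fold change of RPM + 1 (CPF over control) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. The 2 red points, miR-132-3p at 0.87 and miR-212-5p at 0.43, passed an adjusted p of 0.05, and points far to either side, such as miR-34b-3p, include miRNAs at a few reads.

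Both miRNAs that rose belong to 2 of the fixed lists, which overlap. The acetylcholinesterase-linked list takes both arms of miRNA genes that have been linked to that enzyme's transcript. Not every member is therefore known to target it, and whether miR-212-5p does was not tested. In this list, 2 of 9 tested members rose and 7 did not pass. The same 2 passed adjusted over the list alone. miR-186-5p was at 1064 ± 152 RPM in control and 1028 ± 234 in CPF, and miR-125b-5p at 1041 ± 228 and 981 ± 129. As a set the list did not pass (camera, direction up, adjusted p = 0.0527, and adjusted p = 0.158 with an estimated correlation), and its median log2 fold change was -0.01. It took 0.446 ± 0.0467% of RPM in control and 0.524 ± 0.0601% in CPF libraries (permutation p = 0.0039, adjusted p = 0.078). This share contains the 2 miRNAs that rose, so it is no separate evidence for a shift of the list. In the activity-regulated and synaptic list, 2 of 19 tested members rose, 17 did not pass, and 2 passed adjusted over the list alone (camera adjusted p = 0.303). By the mean over all 22 libraries its most abundant members were miR-26a-5p (5628 ± 744 and 5199 ± 507 RPM) and miR-181a (2483 ± 711 and 4074 ± 4541 RPM), the latter placed there by a single CPF library, replicate 1, at 17688 RPM. In control libraries miR-125a-5p (named after its values were seen), at 2855 RPM, was above miR-181a. In the neuron-enriched list, with miR-128 (7674 ± 1352 and 7558 ± 1626 RPM) and the synaptic regulator miR-138-5p (2287 ± 323 and 2295 ± 190 RPM), none of 16 tested members passed (camera direction down, adjusted p = 0.85, median log2 fold change 0.05). Its member miR-153-3p (named after its values were seen) stood in CPF replicate 1 at 14435 RPM, against 282 to 693 RPM in the other 21 libraries.

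Markers of the choroid plexus and ependyma, the secretory and ciliated linings of the ventricles next to the hippocampus, were higher as a set in CPF libraries with camera at its preset correlation (7 members held by all libraries, adjusted p = 0.00036). The set did not pass with an estimated correlation (camera adjusted p = 0.158) or with fry (adjusted p = 0.0757). Nor did it pass without CPF replicates 7, 8 and 9 (6 members, camera adjusted p = 0.276). Those 3 libraries were picked for their high values of these markers, so a weaker result without them is built in. None of the 8 tested members passed over all miRNAs. When adjusted over the list alone, 3 were higher (miR-1298, miR-34b-3p and miR-448-3p, the last named after its values were seen). The log2 fold change was above 0 in 8 of 8, with a median of 1.19, but 3 of the 8 averaged under 3 reads in both groups. Among the members with more reads it ran from 0.37 (miR-204-5p) to 1.83 (miR-448-3p), with miR-34c-5p at 0.57. The list took 0.0907 ± 0.016% of RPM in control and 0.219 ± 0.236% in CPF libraries (permutation p = 0.0152, adjusted p = 0.152). The large spread came from CPF replicates 7, 8 and 9, where miR-1298 stood at 869, 2425 and 3929 RPM against 37.2 to 292 RPM in the other 19 libraries, and the ciliated-cell miRNA miR-34c-5p at 682, 990 and 1839 RPM against 149 to 509 RPM. Without these 3 libraries the list took 0.105 ± 0.0228% in CPF (n = 8), while miR-132-3p (log2 fold change 0.87, limma adjusted p = 0.00622) and miR-212-5p (0.48, adjusted p = 0.00304) still passed.

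**Figure D3:**
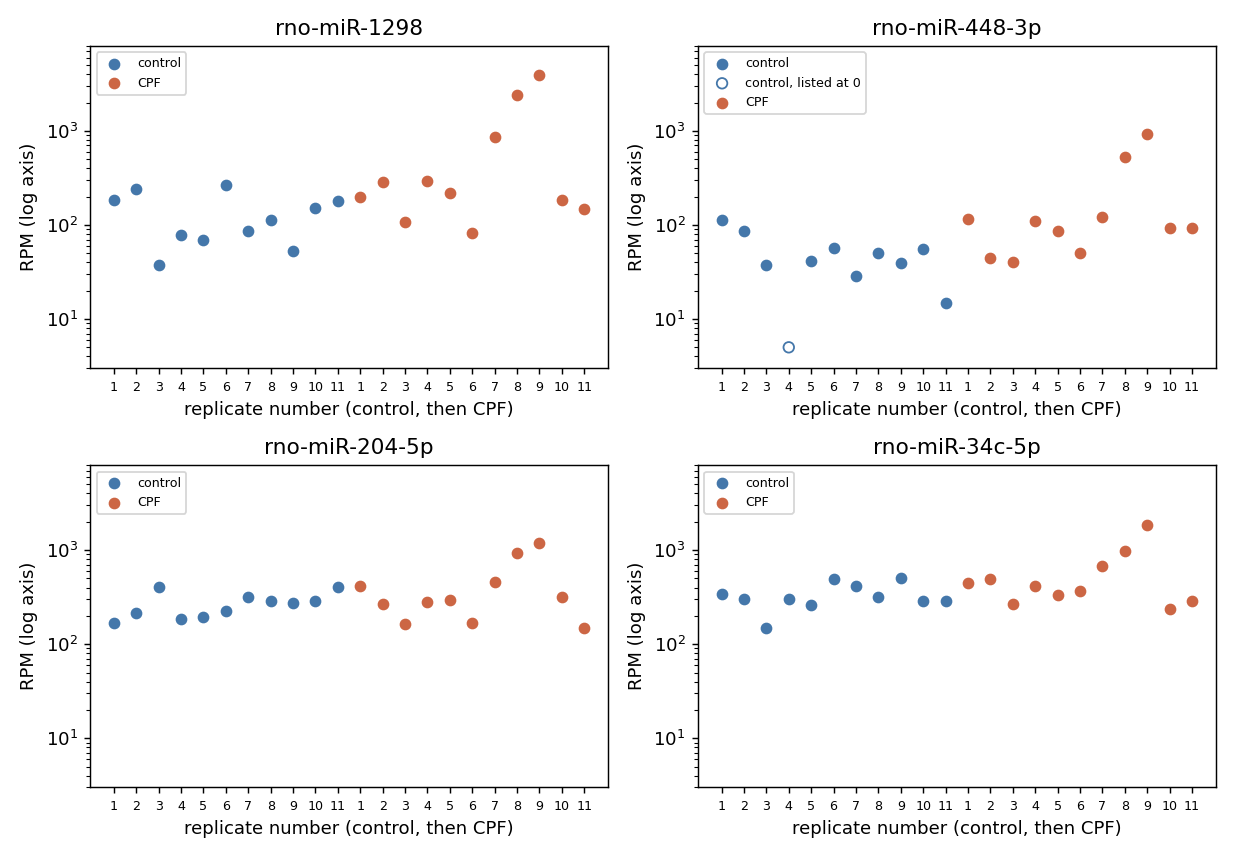
RPM on a log axis of 4 choroid plexus and ependyma list members in each of the 22 libraries, control replicates first and CPF replicates after them, with an open circle for a library listed at 0 (drawn at the foot of the axis). CPF replicates 7, 8 and 9 lie above the other 19 libraries in each panel, with miR-1298 at 869, 2425 and 3929 RPM.

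The miR-30 family was lower as a set in CPF libraries with camera at its preset correlation (10 members held by all libraries, adjusted p = 0.0205), but not with an estimated correlation (adjusted p = 0.158), with fry (adjusted p = 0.126) or without CPF replicates 7, 8 and 9, the libraries high in choroid plexus markers (camera adjusted p = 0.194). None of its 11 tested members passed, over all miRNAs or adjusted over the list alone. Only 2 of the 11 had a log2 fold change above 0, and the median was -0.10. The abundant member miR-30e-5p was at 17124 ± 2155 RPM in control and 15927 ± 1348 in CPF.

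The other lists held no member that passed and did not pass as sets with camera. The microglia and inflammation list (8 tested, adjusted p = 0.973) had miR-22-3p at 4250 ± 803 RPM in control and 4875 ± 410 in CPF (log2 fold change 0.21, limma adjusted p = 0.431) and miR-21-5p at 2599 ± 290 and 2575 ± 392. The oligodendrocyte list (6 tested, adjusted p = 0.628) had miR-338-5p at 2313 ± 350 and 2101 ± 453, and the vessel wall and muscle list (7 tested, adjusted p = 0.973) had the endothelial miR-126a-3p at 1575 ± 186 and 1600 ± 180.7. In the thalamus and hypothalamus list (4 tested, adjusted p = 0.59), miR-182 was at 1040 ± 444 and 1401 ± 888 RPM and miR-7a-1-3p at 270 ± 74.0 and 251 ± 46.8. In the stress and p53 list (6 tested, camera adjusted p = 0.565), which shares its miR-34b and miR-34c names with the choroid plexus list, miR-34b-3p passed adjusted over the list alone, and miR-192-5p was at 567 ± 79.4 and 536 ± 91.3 RPM. The let-7 and miR-98 list (14 tested, adjusted p = 0.647) had let-7i-5p at 30474 ± 2734 and 28802 ± 2556 and let-7f-5p at 1046 ± 172 and 1095 ± 205, and the miR-17 to miR-92 clusters (8 tested, adjusted p = 0.171) had miR-92b-3p at 32099 ± 3827 and 29219 ± 3590 and miR-93-5p at 2499 ± 208 and 2529 ± 287. In the imprinted Dlk1-Dio3 region (30 tested, adjusted p = 0.171), miR-127-3p was at 16919 ± 3319 and 16580 ± 2201 and miR-434-5p at 5860 ± 837 and 6216 ± 457. The miR-181 family (8 tested, adjusted p = 0.303) had miR-181a-5p at 2472 ± 810 and 4023 ± 4499, again with CPF replicate 1 far above the rest, and the miR-29 family (6 tested, adjusted p = 0.647) had miR-29c-3p at 480 ± 104.7 and 448 ± 100. The red blood cell list had a single tested member, miR-144-5p, at 16.5 ± 8.05 and 14.8 ± 17.7 RPM, and miR-144-3p at 6.31 ± 9.51 and 5.06 ± 9.74, all under the floor. For the microglia, vessel wall and miR-29 lists the median log2 fold change (-0.05, 0.04 and 0.03) and the direction of camera (up, down and down) differed in sign. Of 20 per-library measures (list shares, top shares and names detected), 0 differed between groups by a permutation test with adjustment, and 3 had an unadjusted p under 0.05.

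A further question was whether miRNAs differed with the code digit inside a group. In control libraries, 0 of 273 differed between digits 4 and 1 with limma (10 at an unadjusted p under 0.05, and 0 with edgeR on recovered reads, 5 at an unadjusted p under 0.05). The smallest p-values belonged to let-7c-5p (mean 202 RPM at digit 1 and 321 at digit 4), miR-135a-5p (456 and 294 RPM) and miR-666-3p (5.63 and 25.4 RPM, under the floor), each with an adjusted p of 0.917. In CPF libraries, 0 of 273 differed between digits 6 and 3 with limma (19 at an unadjusted p under 0.05), with miR-369-3p (29.2 RPM at digit 3 and 2.3 at digit 6, under the floor), miR-1298 (198 and 1512 RPM) and miR-31a-5p (296 and 175 RPM) at the smallest p-values (adjusted p = 0.588 each). edgeR on recovered reads called miR-1298 there (log2 difference 2.93, adjusted p = 0.0101), and CPF replicates 7, 8 and 9 all carry digit 6. Under the matching assumed above, the difference of the CPF effect between digits had 0 of 273 with limma (11 at an unadjusted p under 0.05) and 0 with edgeR (8 at an unadjusted p under 0.05). miR-30c, miR-30b-5p and miR-28-3p had the smallest p-values there, with differences of 2.16, 0.67 and -0.86 on the log2 scale (limma adjusted p = 0.865 each). Of these, miR-30c averaged 31.3, 59.9, 57.8 and 24.3 RPM at digits 1, 3, 4 and 6, near or under the floor of 31.6 to 62.7 RPM.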

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

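The comparisons on recovered reads with edgeR's TMM, median-ratio scaling, unsummed rows, pseudocount 14, the minimum of 50 RPM and the settings without CPF replicates 7, 8 and 9 were chosen after the data were seen. miR-132-3p kept its direction in all settings run, with log2 fold changes of 0.80 to 0.96 when each library was left out in turn (adjusted p 0.000112 to 0.00403 in 22 of 22) and 0.73 to 1.04 in the others, where it passed in 21 of 22. miR-212-5p did too, at 0.40 to 0.47 (adjusted p 0.00151 to 0.0123 in 22 of 22) and 0.27 to 0.58, passing in 21 of 22. The exceptions were code digit 3 against 1 for miR-132-3p (0.73, adjusted p = 0.484) and 6 against 4 for miR-212-5p (0.27, adjusted p = 0.745), fits on 11 libraries each, so with fewer samples, which called 1 and 1 miRNA. On recovered reads, edgeR called 4 with TMM, 4 with RLE, 4 with totals only and 3 in each of its other settings, limma-voom 3 and DESeq2 5, against 2 with limma, and 2 to 3 when each library was left out. Besides the 2, miR-409b passed in 7 of these 22 settings other than leaving out a single library, and miR-1298 in 6 of 21. Between digits in CPF libraries edgeR called 1 with RLE and 1 with TMM, against 0 with limma. Of the lists, 0 passed with an estimated correlation, 0 with fry and 0 without CPF replicates 7, 8 and 9, against 2. The last setting left out libraries picked for high choroid plexus markers, so a weaker result for that list is built in. At the preset correlation both lists also passed with RLE factors (camera adjusted p = 0.00058 for choroid plexus and ependyma, 0.0225 for miR-30). With median-ratio scaling these were 0.000557 and 0.02025. With the replicate block, 2 miRNAs (miR-132-3p adjusted p = 0.00258, miR-212-5p adjusted p = 0.0286) and 2 lists passed. Same-numbered libraries did not deviate together (correlations -0.247 to 0.348, 4 of 11 over 0.1, and in 0 pairs were both libraries best correlated with their own number). This gave no sign that the numbers pair the samples, but the absence of correlation cannot exclude it. The planned removal of shallow libraries, judged against the median of reads, took out 0 libraries and so moved nothing. In tables simulated at the real depths with 11 libraries against 11, limma found 66.5% of 1.5-fold changes at 5 or more mean reads. These tables held no shifts shared by the miRNAs of a library, so the share may be lower in the real data. Whether depth or the spread between libraries sets this share was not tested.

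Of 41 named miRNAs with a fold change, 20 changed sign in at least 1 setting, 59 times in all. None of these 20 had passed the test in the report, and the cause was not tested. At digit 3 against 1 the log2 fold changes became -0.0461 for miR-143-3p, -0.0458 for miR-27b-3p, 0.0883 for miR-29a-3p, 0.0885 for miR-128, -0.0358 for miR-126a-3p, 0.055 for miR-7a-1-3p, 0.0183 for miR-192-5p, -0.00672 for miR-93-5p, 0.154 for miR-127-3p, 0.0786 for miR-29c-3p, -0.153 for miR-135a-5p, 0.959 for miR-30c, 0.158 for miR-30b-5p and -0.343 for miR-28-3p. At digit 6 against 4 they became -0.108 for miR-138-5p, 0.145 for miR-21-5p, -0.128 for let-7c-5p and -0.212 for miR-31a-5p. Without CPF replicates 7, 8 and 9 they became -0.00648 for miR-143-3p, -0.0166 for miR-27b-3p, 0.0444 for miR-29a-3p, 0.0799 for miR-128, 0.0103 for miR-186-5p, -0.0495 for miR-182, 0.0654 for miR-127-3p and 0.239 for miR-30c. In edgeR miR-128 was at 0.00366 and miR-21-5p at 0.0196 with TMM and with the robust fit, and miR-138-5p at -0.00383 with RLE, -0.0106 with upper quartile and -0.0151 with no filter. In limma-voom miR-21-5p was at 0.0125 and miR-127-3p at 0.0132. Leaving out each library in turn gave -0.0804 to 0.00891 for miR-29a-3p, -0.0836 to 0.019 for miR-128, -0.0143 to 0.0446 for miR-138-5p, -0.055 to 0.0322 for miR-21-5p, -0.00761 to 0.0519 for miR-126a-3p, -0.0115 to 0.0471 for miR-93-5p, -0.0616 to 0.0251 for miR-127-3p and -0.25 to 0.0338 for miR-30c.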

Other observations

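The tests on minor arms, on the libraries with high choroid plexus markers, on the 7-member score, on miR-181b, of chi-square without 3 names and on the thalamus and hypothalamus share were chosen after the values were seen; the splits, the list score and depth covariates and the rank correlation were chosen before. From the miR-132 gene nearly all reads came from the 3p arm (97.9% in control and 98.2% in CPF libraries), and from the neighbouring miR-212 gene from the 5p arm (96.6% and 96.2%). Across libraries no relation between the levels of miR-132-3p and miR-212-5p was detected within a group. In the 11 control libraries Pearson's r was 0.05 (permutation p = 0.889, adjusted p = 0.927) and Spearman's rho -0.23 (permutation p = 0.506, adjusted p = 0.776), and r was -0.59 without the 2 libraries farthest from the median of miR-132-3p. In the 11 CPF libraries r was 0.03 (permutation p = 0.927) and rho 0.10 (permutation p = 0.776), and r was 0.04 without the 2 farthest. Both relations of this family rest on 11 libraries at 49 to 95 mean reads per library. Counting error at such depth can hide a shared variation, so these values cannot show that the 2 miRNAs vary independently. The 5 or 6 libraries per code digit are too few to give the relations within digits.

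The rise of miR-132-3p and miR-212-5p in CPF libraries was weighed against chance, depth and tissue from outside the hippocampus. Of 100 splits of the 22 libraries into 11 and 11, the real split included, 2 gave 2 or more miRNAs past the threshold. The real split gave 2, the highest other also 2, and 3 of the others gave any call. This share, under 0.05, argues against chance but does not exclude it, and the splits took no account of the code digits. With log2 reads as a covariate the larger adjusted p of the pair was 0.00544 (limma), which argues against depth. Against choroid plexus tissue, the larger adjusted p was 0.00622 without CPF replicates 7, 8 and 9. With the list score as a covariate, miR-132-3p passed (adjusted p = 0.0189), but miR-212-5p did not (adjusted p = 0.0852), since its SE grew from 0.0864 to 0.115 while its log2 fold change went from 0.43 to 0.44; with a score of the 7 members held by all libraries, as control replicate 2 lacks a low member, it passed (log2 fold change 0.44, SE 0.105, adjusted p = 0.0351). A biological hypothesis is that CPF may raise the shared primary transcript, but the summed minor arms, 43.7 ± 24.0 RPM in control and 66.6 ± 44.7 in CPF (ratio 1.52, 95% bootstrap interval 0.898 to 2.49, permutation p = 0.153), are too near the floor to decide, and the unexplained code digit and the unassigned fear conditioning cohorts also stay open.

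CPF replicates 7, 8 and 9 stood above each of the other 19 libraries in 12 of 12 values of miR-1298, miR-448-3p, miR-204-5p and miR-34c-5p, for example 454, 940 and 1191 RPM of miR-204-5p against 149 to 411 RPM. Without them the log2 fold change was 0.65 for miR-1298 (95% CI -0.06 to 1.36) and 1.18 for miR-448-3p (95% CI -0.09 to 2.45), against 1.61 and 1.83 with them, and -0.10 for miR-204-5p and 0.13 for miR-34c-5p, but the 3 libraries were picked for their high values of these markers, so a fall is built in and a change by CPF in every treated rat stays open. Choroid plexus or other tissue carried along in dissection may be the source, but since those 4 markers had been picked for the pattern, the other 9 list members in the files were summed. They were above the highest of the other 19 libraries (216 RPM) in 2 of the 3, at 241 and 355 RPM in replicates 7 and 9, and not in replicate 8 at 186 RPM (median of the others 155 RPM), so choroid plexus tissue is left undecided. The thalamus and hypothalamus list moved with the markers, mainly through miR-182, at 0.199, 0.288 and 0.397% of RPM in replicates 7, 8 and 9, above the highest of the other 19 (0.250%) in 2 of the 3, which leaves thalamus or hypothalamus tissue undecided too, the neuron-enriched list had its lowest shares there (1.298, 1.167 and 1.064% against 1.304% or more), and a response of the choroid plexus in some treated rats was not tested.

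In CPF replicate 1 summed miR-181a and miR-181a-5p, which carry near-identical mature sequences, stood at 35176 RPM, 7.05 times the median of the other 21 libraries (range 2569 to 8205 RPM), and miR-153-3p (named after its values were seen) at 14435 RPM, 32.0 times their median (range 282 to 693 RPM). These 3 names exceeded 3 times the highest of the other libraries, at over 200 RPM, and no other library had such a name. More of the transcripts that miR-181a shares with miR-181b is argued against, as summed miR-181b was 516 RPM, inside the range of the others (274 to 1043 RPM). A broad shift of the library stays open: its rank correlation with the mean of the others (0.964) cannot decide, as all 22 lay between 0.942 and 0.970, and its median chi-square per degree of freedom against the other libraries, 28.6 and the highest of the 22, was still 13.2 without the 3 names, above the median of the 22 (5.03) and under the highest (16.8). Over all names the next highest median chi-square, 17.3, was that of control replicate 7, so unlike libraries were not confined to CPF. Control replicate 7 also had the largest oligodendrocyte list share of the 22, at 9.04% of RPM. For CPF replicate 1, an uneven amplification or ligation, carry-over from another library and a trait of this rat were not tested.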
